A study of Caenorhabditis elegans with 4 samples.

How the data were processed

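RNA was measured in 4 samples of whole wild-type worms, 2 controls, untreated per the series label, and 2 treated with 1 mM MAHMA NONOate and left for 4 h at 20 °C. Per the labels' protocols, libraries were made with the Illumina TruSeq RNA kit, which selects polyadenylated RNA, from total RNA extracted with Trizol. TopHat2 2.0.2, Cufflinks 2.0.5 and R 2.15.2 are named in the submitters' processing notes, without their settings. The genome build, the gene annotation and the scaling between libraries are not given in the sources used here, so no coordinates are printed.

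The authors deposited 1 table of their own comparison, with a control and an NO value for each locus, per the file headers. The authors' values per condition were taken as FPKM, which scales fragments by transcript length and library size, because the column layout is that of a Cufflinks comparison and the values were not whole and differed in sum between conditions. The unit itself is not named in the table. The deposited fold change is the ratio of the NO to the control value, which held within 0.1 percent for all 15621 loci above 0 in both conditions. The deposited log2 fold is its logarithm, with a placeholder where a value is 0. The deposited test statistic is a score whose sign is opposite to the fold in all 15621 loci. The deposited p-value equalled the normal two-sided tail of that score within 0.001 in all 15621 loci, and the adjusted p equalled a Benjamini-Hochberg adjustment over all 16562 loci to within 3.4e-06.

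Replicates had been combined before deposit, so count models, limma and camera could not be run and the fallback fixed in the design was used. Calls are those of the deposited adjusted p at 0.05, with no test of single genes added. An SE was computed for each locus as the deposited log2 fold divided by the test statistic. The depth is unknown, since low values showed no whole-read steps, and no counting interval is given. Precision can be read from the implied SE, whose smallest value was 0.25 on the log2 scale, so that a 95 percent interval spans at least a 1.41-fold change each way. The summed values were 1355750 FPKM in control and 1284080 FPKM in NO, and the 10 most abundant loci held 9.90% and 9.65% of them. Across the kept loci the Pearson correlation of log2(FPKM + 1) between conditions was 0.93, where loci are not independent replicates.

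Gene names came from the table. They were matched to current symbols through a reference gene table (assembly WBcel235), used only for names, gene classes and the order of neighbouring genes. Of 16562 loci, 15731 matched, 601 named loci did not and 230 had no name. A further property of the table is that 1231 loci join several genes, whose values cannot be separated, and 241 loci share identical values with another locus. Loci at 0 in one condition (659 in control only, 282 in NO only) have no fold, and 0 of them were called.

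A fold set by list was the log2 ratio of NO to control after adding 1 FPKM to each, which understates changes of weakly expressed genes, over the 14285 loci with a mean of at least 1 FPKM. For 40 gene lists on stress, immunity, metabolism, germline and tissues, the median ratio was placed as a percentile among 10000 random lists of the same size, matched on mean abundance in 10 bins. Calls inside and outside each list were compared by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 40 lists. Deposited p-values were also adjusted over each list alone. The list of transporters for foreign compounds held ABC transporters of the pgp, mrp and haf families. Groups, tests, lists, the named-gene rule and most processing alternatives were set before the data were examined.

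Genes named in the text followed a rule. It took the 12 largest rises by the log2 ratio after adding 1 FPKM and all falls among called loci, up to 4 members of each list (called members by size of change, then the most abundant), and a fixed set: hsp-16.1, hsp-16.2, hsp-16.41, hsp-70, hsp-12.6, sod-3, mtl-1, mtl-2, gst-4, cysl-2, ftn-1, daf-16, hsf-1, skn-1, hif-1, hsp-4 and hsp-6. Genes outside it, among them vit-3 and most genes of the closing section, were chosen after their values were seen.

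Alternatives were adjusted p thresholds of 0.01 and 0.1, a minimum fold of 2, a minimum mean of 10 FPKM or none, a pseudocount of 0.1 or none, centring on the median, and unmatched random lists. Added after seeing the data were re-adjustment over loci of at least 1 FPKM, centring on the median of each abundance bin, and leaving out joined, duplicate or ribosomal RNA loci. Calling was tested on simulated data with the implied SE of the 15621 loci. Changed genes were drawn only from loci with a mean of at least 1 FPKM and without the largest SEs. Of 50 genes each, 6%, 62%, 80% and 94% were called at true log2 changes of 1, 2, 3 and 4, and 0.026% of unchanged loci. The noise was normal with the same SE that the test used. The share of unchanged loci called therefore follows from the setup, and the other shares do not cover the weakest loci. In the list test, a simulated list of 30 genes shifted by 0.5 reached the 100th percentile and 2 of 100 unshifted lists fell outside the central 95%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.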

Results

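Wild-type Caenorhabditis elegans, a free-living nematode, were exposed to nitric oxide (NO) at the L4 stage, the last larval stage before adulthood. The NO source was 1 mM MAHMA NONOate, a compound that releases NO in solution, and RNA was taken from whole worms after 4 h of recovery at 20 °C. RNA was sequenced from 2 control samples, untreated per the series label, and 2 NO-treated samples. The protocol text is the same for both groups and does not say whether controls were handled in parallel without the NO donor, so handling and the donor compound are not separated from NO. The series was designed to compare the transcripts of treated and untreated worms. The authors' deposited table gave 1 abundance per condition for each of 16562 loci, read here as FPKM, with the fold change, a test statistic, a p-value and an adjusted p. Values of single libraries were not analysed here, so the spread between replicates and the depth of each library are unknown. Every standard error (SE) given is the one implied by the deposited test statistic. Nothing in the labels says whether the 2 samples of a condition came from separate cultures, so the p-values may measure technical spread.

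NO was followed by more rises than falls in transcript level. An adjusted p of 0.05 was passed by 66 loci in the authors' deposited table, of which 64 were higher after NO and 2 were lower. The 64 higher loci had a median deposited fold of 5.43, with a range from 2.35 to 112.7. Of them, 43 were over 4-fold, 17 were over 10-fold and 12 had a control value under 1 FPKM. At an unadjusted p under 0.05 the deposited table held 456 higher and 56 lower loci, or 3.09% of all loci, against 828.1 that chance alone would give. At an unadjusted p under 0.01 the table held 219 higher and 17 lower loci, more than chance alone would give. The shortfall therefore did not extend to 0.01, and rises far outnumbered falls at both thresholds. Fewer p-values under 0.05 than chance gives mean that the deposited test was conservative at that threshold, taken over all loci and both directions. A list without any p under 0.05 is therefore weak evidence that its genes did not change. The median log2 ratio was -0.03 over the 14285 loci with a mean of at least 1 FPKM, a value that scaling between libraries may set. The median depended on abundance, with deposited log2 folds of 0.13 at 1 to 10 FPKM, -0.09 at 10 to 100 FPKM and -0.14 above 100 FPKM. Precision limited the calls among weakly expressed loci, since the implied SE of a log2 fold had medians of 0.70, 0.44 and 0.34 in those ranges.

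**Figure D1:**
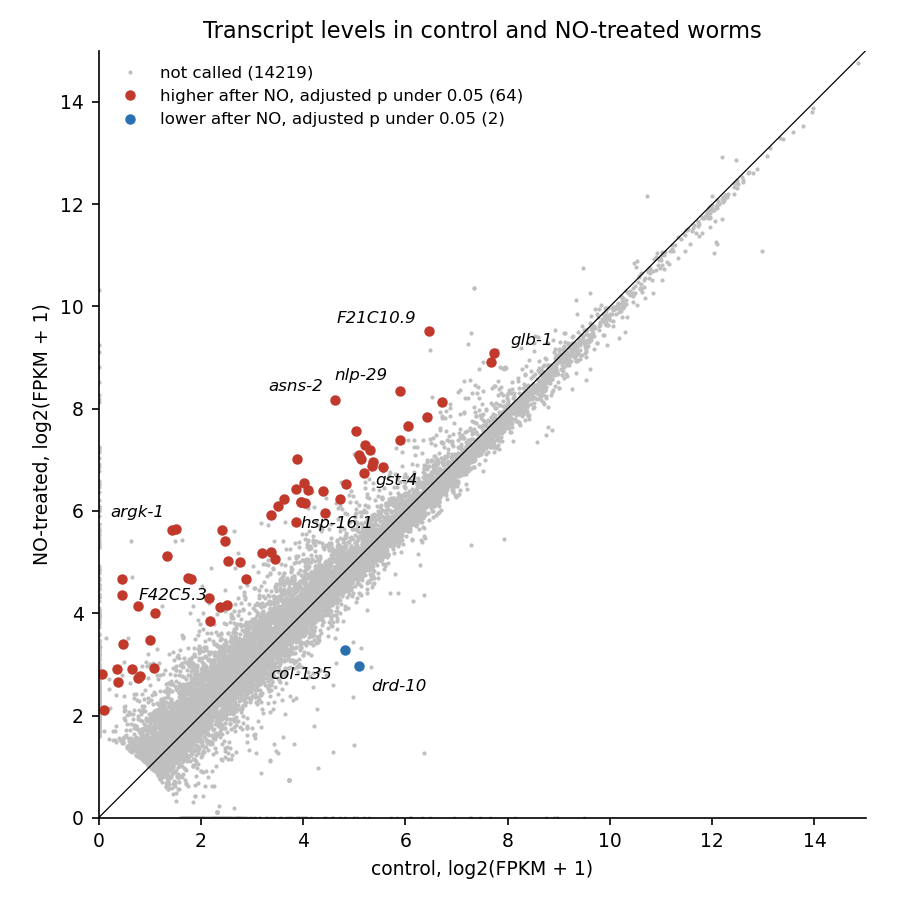
Abundance in NO-treated worms (vertical axis) against control worms (horizontal axis), both as log2(FPKM + 1), for the 14285 loci with a mean of at least 1 FPKM, with the line of equal values. Red points are the 64 loci called higher and blue points the 2 called lower at an adjusted p under 0.05, and the 64 higher loci lie above the line.

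The 12 largest rises among called loci, ranked by the log2 ratio after adding 1 FPKM to each condition, included enzymes, an antimicrobial peptide and genes known only by sequence name. F42C5.3 rose from 0.367 to 24.4 FPKM in the authors' deposited table, a log2 fold of 6.06 (SE 0.94, adjusted p = 2.31e-07). The arginine kinase gene argk-1, listed as F44G3.2, rose 26.2-fold, from 1.88 to 49.1 FPKM in the deposited table (log2 fold 4.71, SE 0.57, adjusted p listed as 0). For asns-2, an asparagine synthetase gene, the deposited values were 23.8 and 289 FPKM, a 12.13-fold rise with an adjusted p listed as 0. F21C10.9 was already abundant in control worms and rose from 86.8 to 732 FPKM in the deposited table, 8.44-fold, again with an adjusted p listed as 0. H20E11.2 rose 51.01-fold, srlf-34 (listed as ZK970.7) 21.7-fold and Y47H9C.1 23.6-fold in the deposited table, from control levels of 0.381, 1.55 and 0.710 FPKM. T05H4.4 and F22B8.7 rose 11.2-fold and 9.27-fold in the same deposited table, with adjusted p of 1.4e-06 and 8.92e-11. The other 3 of the 12, cnc-4, F44E5.4 and gst-35, are given with their groups. By deposited fold alone some loci with low control values, such as best-2 (112.7-fold) and F14F9.3 (40.5-fold), ranked above several of these 12, and these 2 were chosen after their values were seen. Both falls were of moderately expressed genes. drd-10, listed as C33G8.3, fell from 33.02 to 6.79 FPKM in the deposited table (log2 fold -2.28, SE 0.54, adjusted p = 0.00911), and the cuticle collagen gene col-135 fell from 27.1 to 8.73 FPKM (log2 fold -1.63, SE 0.37, adjusted p = 0.00497).

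Some small heat shock protein and HSP70-family genes rose, and others were not called. Of 14 measured small heat shock protein genes, 4 rose, and 6 passed when adjusted over the list alone. hsp-16.1 rose from 11.4 to 74.5 FPKM in the authors' deposited table (log2 fold 2.71, SE 0.59, adjusted p = 0.00196), and hsp-16.11 from 13.4 to 85.004 FPKM (adjusted p = 0.00101). hsp-16.48 and hsp-16.49 had identical deposited values, 14.5 and 71.1 FPKM (adjusted p = 0.0202). Within each of these 2 pairs the genes are near-identical copies, so how reads were split between them is uncertain. hsp-16.2 was listed at 2.09 and 10.86 FPKM (adjusted p = 0.916) and hsp-16.41 at 3.11 and 15.1 FPKM (adjusted p = 0.482) in the deposited table, and these 2 passed only when adjusted over the list alone (adjusted p = 0.0363 and 0.0148). hsp-12.6 had deposited values of 6.07 and 4.08 FPKM and was not called. A larger share of the list was called than of the other loci (Fisher's exact test, two-sided, adjusted p = 8.04e-06 over 40 lists, or 0.00034 with loci of identical values counted once), and its median log2 ratio of 0.21 lay at percentile 99.6 of abundance-matched random lists. Counting identical loci once still left hsp-16.1 and hsp-16.11 as 2 calls, so the 4 calls may be as few as 2 signals. Among 23 cytosolic chaperone and co-chaperone genes, 2 rose over all loci and 2 when adjusted over the list alone. These were the neighbouring HSP70-family genes F44E5.4, at 2.35 and 24.9 FPKM, and F44E5.5, at 2.503 and 24.34 FPKM, in the deposited table (log2 folds 3.41 and 3.28, SE 0.53 and 0.52, adjusted p = 2.31e-07 and 6.28e-07), which also share near-identical sequence. hsp-70 went from 0.424 to 3.30 FPKM in the deposited table but missed the threshold (unadjusted p = 0.0194, adjusted p = 0.99994), while hsp-1, the constitutive HSP70, was listed at 1715 and 1637 FPKM. Enrichment of the chaperone list (Fisher's exact test, adjusted p = 0.04) rested only on F44E5.4 and F44E5.5, which may share reads and so count 1 signal as 2 calls. It was also lost among loci of at least 10 FPKM (adjusted p = 0.0562). The list's median of -0.09 lay at percentile 76.5.

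Markers of unfolded protein stress in the endoplasmic reticulum (ER) and in mitochondria were not called. Of 22 ER stress genes, 0 passed over all loci and 0 adjusted over the list alone, with 1 higher and 0 lower at an unadjusted p under 0.05 in the deposited test. The ER chaperone gene hsp-4 had deposited values of 162 and 144 FPKM, and the list's median of -0.11 lay at percentile 42.4. The 11 mitochondrial genes gave 0 calls by either adjustment and 0 at an unadjusted p under 0.05, with a median of -0.17 at percentile 23.1. Their marker hsp-6 was listed at 350 and 334 FPKM in the authors' deposited table. All 30 proteasome subunit genes had ratios below 0, with a median of -0.16 at percentile 19.4 and 0 calls by either adjustment or at an unadjusted p under 0.05.

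Single detoxification genes rose, within lists whose enrichment among the calls did not pass Fisher's exact test after adjustment. In the lists with a call, the odds of a call were 5.19 to 13.4 times those of the other loci. So few calls leave enrichment undecided. gst-35 rose from 4.55 to 41.7 FPKM in the authors' deposited table (log2 fold 3.19, SE 0.57, adjusted p = 2.43e-05), and gst-4 from 32.99 to 134.9 FPKM (log2 fold 2.03, SE 0.40, adjusted p = 0.000375). They were the 2 called among 35 glutathione S-transferase genes, of which 3 passed when adjusted over the list alone. Ratios of 26 members were above 0, and the median of 0.22 lay at percentile 99.8 (Fisher's exact test on the calls, adjusted p = 0.0756). The list of SKN-1 targets and phase 2 detoxification genes had 19 measured members and gst-4 as its 1 call, with a median of 0.17 at percentile 99.4. Adjusted over the list alone, 4 were higher and 1 was lower (Fisher's exact test, adjusted p = 0.322). The lower one, cyp-35A2, was listed at 37.3 and 15.7 FPKM in the deposited table and was picked out after its values were seen. Of 50 UDP-glucuronosyltransferase genes 2 rose, and 4 passed adjusted over the list alone (Fisher's exact test, adjusted p = 0.128, median 0.09, percentile 90.8). These 2 were ugt-31, at 10.002 and 32.4 FPKM, and ugt-24, in a locus joined with a small RNA gene, at 3.49 and 18.7 FPKM in the deposited table. cyp-14A5 was the 1 call among 43 cytochrome P450 genes, at 16.05 and 84.0 FPKM in the deposited table (log2 fold 2.39, SE 0.39, adjusted p = 1.08e-06). Adjusted over the list alone, 2 P450 genes were higher and 2 lower (median -0.07, percentile 4.52; Fisher's exact test, adjusted p = 0.517). Transporters of the ABC family (29 genes) had 0 calls over all loci, 3 higher adjusted over the list alone and 5 higher and 0 lower at an unadjusted p under 0.05, with a median of 0.26 at percentile 99.6.

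Genes that are higher when the transcription factor DAF-16 is active were enriched among the calls, without several of its standard markers. Of 22 measured genes 4 rose and 6 passed adjusted over the list alone (Fisher's exact test, adjusted p = 3.81e-05, median 0.06, percentile 97.4). Ratios of 11 were above 0 and of 11 below. The median depended on the abundance filter, at 0.31 (100th percentile) among loci of at least 10 FPKM and 0.16 (percentile 99.6) with no filter. The called members were the long noncoding RNA tts-1 (15.5 and 69.9 FPKM, adjusted p = 0.0448), gst-4, the peroxisomal catalase gene ctl-2 (40.2 and 124 FPKM, adjusted p = 0.00472) and the glyoxylate cycle gene gei-7 (46.2 and 115 FPKM, adjusted p = 0.0257) in the authors' deposited table. The metallothionein gene mtl-1 narrowly missed the threshold at 3.61 and 28.6 FPKM in the deposited table (log2 fold 2.99, SE 0.80, adjusted p = 0.05001). sod-3, a manganese superoxide dismutase gene, had deposited values of 4.05 and 3.08 FPKM and was not called. Transcripts of the regulators themselves had deposited log2 folds of -0.06 (SE 0.40) for daf-16, -0.16 (SE 0.37) for hsf-1 and -0.12 (SE 0.43) for skn-1, none of them called. hif-1 was not analysed here. The 12 genes that are lower under active DAF-16 gave 0 calls by either adjustment, with 3 higher and 1 lower at an unadjusted p under 0.05 in the deposited test (median -0.07, percentile 63.4). Their median turned to 0.09 at percentile 97.51 among loci of at least 10 FPKM. Of 33 antioxidant and thiol redox enzyme genes, ctl-2 was the 1 call and 2 passed adjusted over the list alone. Their median of -0.06 lay at percentile 86.2 (Fisher's exact test, adjusted p = 0.437), and the abundant members sod-1 (411 and 418 FPKM) and prdx-2 (892 and 834 FPKM) were not called in the deposited table. gst-4 belongs to 3 of these lists and ctl-2 to 2, so the lists are not independent.

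**Figure D2:**
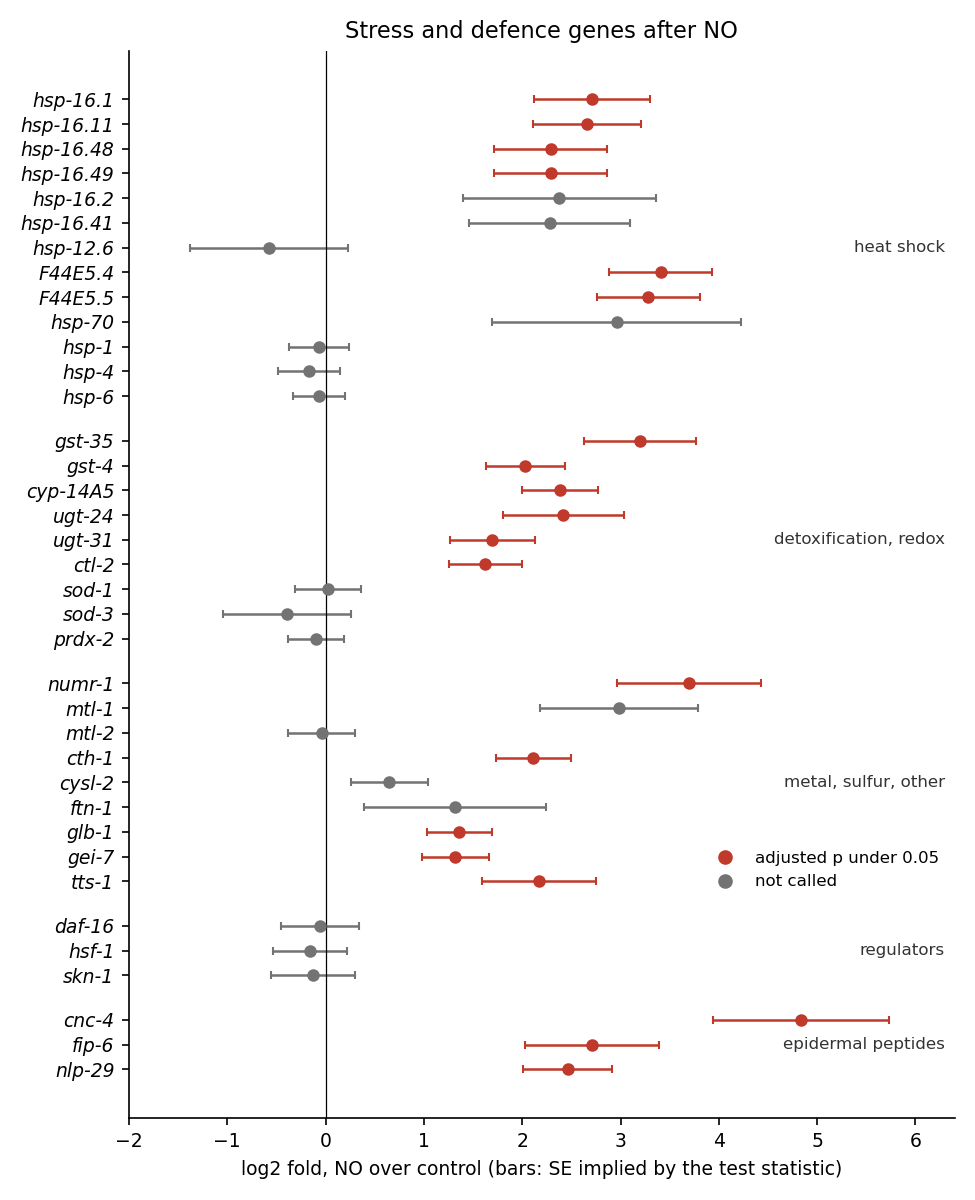
Deposited log2 fold of NO over control (horizontal axis) for stress, detoxification, metal, regulator and epidermal peptide genes, with bars of 1 SE implied by the deposited test statistic. Red points passed an adjusted p of 0.05 and grey points did not, and daf-16, hsf-1 and skn-1 lie within 1 SE of 0.

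Single genes of metal, sulfur and oxygen handling rose within lists whose enrichment did not pass Fisher's exact test. With 1 call in each list that test could not decide. The odds of a call were 11.5 to 13.7 times those of the other loci (Fisher's exact test, unadjusted p = 0.0757 to 0.0885). numr-1, a metal-responsive gene, rose from 1.16 to 15.1 FPKM in the authors' deposited table (log2 fold 3.70, SE 0.73, adjusted p = 0.000353). It was the 1 call among 20 iron, heme and metal genes, of which 3 passed adjusted over the list alone (median 0.19, percentile 96.4; Fisher's exact test, adjusted p = 0.322). The metallothionein gene mtl-2 was listed at 499 and 485 FPKM and the ferritin gene ftn-1 at 0.836 and 2.08 FPKM in the deposited table, and neither was called. cth-1, which encodes a cystathionine gamma-lyase, rose from 36.1 to 156 FPKM in the deposited table (log2 fold 2.11, SE 0.38, adjusted p = 3.2e-05). It was the 1 call, over all loci and adjusted over the list alone, among 17 HIF-1 targets and sulfide genes (median 0.06, percentile 83.6; Fisher's exact test, adjusted p = 0.322). The HIF-1 target cysl-2, listed as K10H10.2, had deposited values of 56.1 and 88.0 FPKM and was not called (log2 fold 0.65, SE 0.39). The globin gene glb-1 rose from 211 to 543 FPKM in the deposited table (log2 fold 1.36, SE 0.33, adjusted p = 0.0139). It was the 1 call by either adjustment among 20 globin and soluble guanylyl cyclase genes, whose products bind or sense gases through heme (median -0.0029, percentile 23.8; Fisher's exact test, adjusted p = 0.322).

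Several epidermal antimicrobial peptide genes rose, and single genes rose in other immune lists. cnc-4 rose from 1.69 to 48.4 FPKM (log2 fold 4.84, SE 0.90, adjusted p = 6.01e-05), nlp-29 from 58.9 to 325 FPKM (log2 fold 2.46, SE 0.45, adjusted p = 5.1e-05) and fip-6 from 4.80 to 31.3 FPKM (adjusted p = 0.0212) in the authors' deposited table. These were 3 of 40 measured genes, 6 passed adjusted over the list alone, and 31 had ratios above 0 (Fisher's exact test, adjusted p = 0.00824). The median of 0.34 lay at the 100th percentile of random lists. fipr-21, the most abundant member, had deposited values of 807 and 688 FPKM and was not called. In the intracellular pathogen response list, pals-14 (listed as F22G12.1) was the 1 call among 23 genes, at 0.282 and 6.47 FPKM in the deposited table (adjusted p = 0.00116). Adjusted over the list alone, 4 passed (median 0.24, percentile 95.2; Fisher's exact test, adjusted p = 0.337). That median was 0.50 (percentile 99.99) with no abundance filter and 0.35 (percentile 97.7) without joined loci. Among loci of at least 10 FPKM it was 0.02 (percentile 84.9). clec-174 was the 1 call by either adjustment among 92 C-type lectin genes, at 0.299 and 5.29 FPKM in the deposited table (adjusted p = 0.0015; list median -0.01, percentile 40.4; Fisher's exact test, adjusted p = 0.927). The 25 innate immune effector genes, mostly of the intestine, gave 0 calls by either adjustment and 0 at an unadjusted p under 0.05, with a median of 0.10 at percentile 98.1. That list lay inside the central 95% with unmatched random lists (percentile 92.5) and without joined loci (percentile 97.1).

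Most cuticle collagen genes of low and middle abundance had higher values after NO, though few were called singly. Of 128 measured collagen genes 7 rose and 1 fell, and adjusted over the list alone 41 were higher and 3 lower (Fisher's exact test, adjusted p = 4.96e-06). Their median log2 ratio of 0.56 lay at the 100th percentile of random lists, whose central 95% ran from -0.14 to -0.04. col-14 rose from 34.2 to 129 FPKM (log2 fold 1.91, SE 0.46, adjusted p = 0.0109), col-109 from 9.39 to 35.6 FPKM (adjusted p = 0.021), col-104 from 27.6 to 90.8 FPKM (adjusted p = 0.00932) and dpy-5 from 35.4 to 106 FPKM (adjusted p = 0.0239) in the authors' deposited table. Direction depended on abundance, although the 3 genes lower when adjusted over the list alone lay below 1000 FPKM. These were col-135, col-101 (743 and 375 FPKM) and col-143 (776 and 439 FPKM), the last 2 picked out after their values were seen. Ratios were above 0 for 61 of 76 collagen genes with a mean of 1 to 100 FPKM (median 0.81) and for 29 of 36 at 100 to 1000 FPKM (median 0.59), but for 2 of 16 above 1000 FPKM (median -0.34). All loci above 1000 FPKM had a median of -0.11. One of these abundant collagens, the adult-stage gene col-19, was listed at 2294 and 1808 FPKM in the deposited table. The molting cycle list of 15 genes gave 0 calls over all loci and 1 adjusted over the list alone, grl-21, with 3 higher and 0 lower at an unadjusted p under 0.05 in the deposited test (median 0.47, percentile 99.6). Among loci of at least 10 FPKM the molting median was 0.38 at percentile 97.44, inside the central 95%. The 10 hypodermis genes gave 0 calls by either adjustment and 1 higher at an unadjusted p under 0.05 (median 0.08, percentile 93.2).

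**Figure D3:**
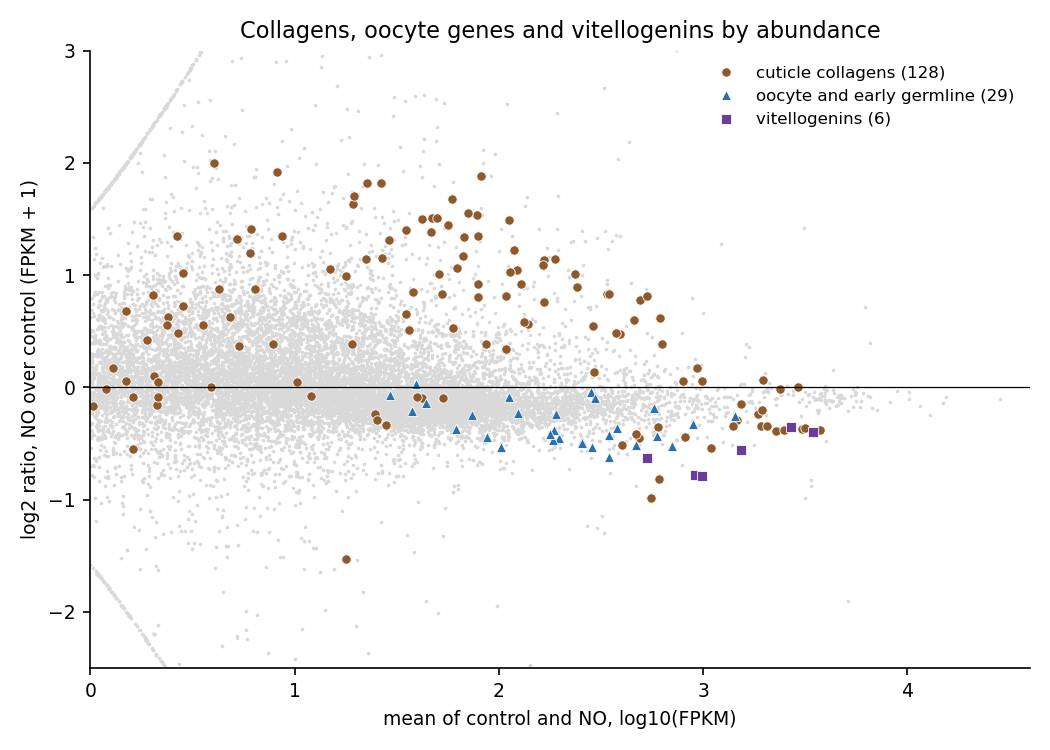
Log2 ratio of NO over control, computed on FPKM + 1 (vertical axis), against the log10 mean of both conditions (horizontal axis), for all loci (grey), 128 collagen genes (brown circles), 29 oocyte and early germline genes (blue triangles) and 6 vitellogenin genes (purple squares). Most collagens under 1000 FPKM lie above 0 and 14 of the 16 above it lie below 0, as do 28 of the oocyte genes and all 6 vitellogenins, and 233 grey points fall outside the plotted range.

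Yolk, oocyte and cell cycle genes lay lower after NO as lists, with 0 single genes called over all loci. All 6 vitellogenin genes, which encode yolk proteins, had ratios below 0 (median -0.59, percentile 0), and 2 passed adjusted over the list alone. These were vit-4, at 1248 and 723 FPKM in the authors' deposited table (log2 fold -0.79, SE 0.31, adjusted p = 0.69 over all loci), and vit-3, at 1150 and 669 FPKM, while vit-6, the most abundant, was listed at 3948 and 3003 FPKM (log2 fold -0.39, SE 0.37). vit-3 and vit-4 had close values (log2 folds -0.78 and -0.79) and may count 1 signal as 2. Shared reads between them were not tested. At an unadjusted p under 0.05 the deposited test gave 0 higher and 3 lower vitellogenins. Ratios of 28 of 29 oocyte and early germline genes were below 0 (median -0.37, percentile 0), with 0 passing adjusted over the list alone and 1 lower at an unadjusted p under 0.05. Its 4 named genes, none called, were the RNA helicase gene cgh-1 (1556 and 1302 FPKM, log2 fold -0.26), the RNA-binding protein gene car-1 (996 and 794 FPKM) and the eggshell genes perm-2 (827 and 575 FPKM) and perm-4 (682 and 503 FPKM) in the deposited table. For all 23 cell cycle and DNA replication genes the ratio was below 0 (median -0.33, percentile 0), with 0 passing by either adjustment or at an unadjusted p under 0.05. In the deposited table pcn-1 was listed at 419 and 326 FPKM, rnr-2, a ribonucleotide reductase subunit gene, at 322 and 218 FPKM, cyb-1 at 247 and 229 FPKM and air-1 at 228 and 187 FPKM (log2 folds -0.36, -0.57, -0.11 and -0.29). The 21 DNA damage response genes had a median of -0.24 at percentile 0.16, with 20 ratios below 0 and 0 calls by either adjustment or at an unadjusted p under 0.05. Sperm genes lay apart from these lists, with a median of 0.10 over 74 genes at the 100th percentile, 44 ratios above 0, 0 calls by either adjustment and 2 higher and 0 lower at an unadjusted p under 0.05. The 58 histone genes had a median of 0.05 at percentile 40.3, with 0 calls by either adjustment and 1 higher at an unadjusted p under 0.05.

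The lists of energy metabolism, protein synthesis and autophagy genes held 0 called genes. Single metabolic genes outside these lists, such as argk-1 and gei-7, were called higher. Mitochondrial electron transport and ATP synthase genes had 44 of 45 ratios below 0, with a median of -0.14 at percentile 36.3. The median was -0.18 for 20 glycolysis and gluconeogenesis genes (percentile 11.6) and -0.17 for 27 fatty acid genes (percentile 9.71). Ribosomal protein genes had a median of -0.08 over 76 loci at percentile 99.4, but 31 of those loci joined several genes, and the percentile was 78.9 without joined loci. For 23 autophagy and lysosome genes the median of -0.07 lay at percentile 81.1. In these 5 lists 0 genes passed over all loci or adjusted over the list alone, and an unadjusted p under 0.05 was reached by 0 higher and 0 lower genes except for 3 lower fatty acid genes in the deposited test. As examples, the authors' deposited table listed rpl-39 at 12198 and 10899 FPKM, aldo-2 at 758 and 601 FPKM and elo-1 at 748 and 640 FPKM.

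The remaining tissue and family lists gave 0 calls over all loci. The 76 pharynx genes, mostly of the pqn and abu families, had a median of 0.14 at percentile 99.96, 0 calls by either adjustment and 8 higher and 0 lower at an unadjusted p under 0.05 in the deposited test. Body wall muscle genes (18) had a median of 0.02 at percentile 99.1 with 0 calls by either adjustment and 0 at an unadjusted p under 0.05. The median was 0.0022 at percentile 95.4 without joined loci. The 17 intestine genes had a median of 0.03 at percentile 95.7, 0 calls over all loci, 1 adjusted over the list alone (mtl-1) and 2 higher at an unadjusted p under 0.05. Neuronal genes (21) had a median of 0.09 at percentile 88.9 with 0 calls by either adjustment and 0 at an unadjusted p under 0.05. Insulin-like peptide genes (29) had a median of 0.24 at percentile 96.7, with 0 calls by either adjustment and 1 higher at an unadjusted p under 0.05. The 203 F-box, MATH and BTB genes had a median of -0.016 at percentile 0.455, with 0 calls by either adjustment and 5 higher and 0 lower at an unadjusted p under 0.05. That median turned to 0.030 without the filter on low expression. The list lay inside the central 95% with unmatched random lists (percentile 71.8) and among loci of at least 10 FPKM (percentile 10.6). Over the 40 lists, 12 medians lay above and 5 below the central 95% of random lists, where chance would place 2 in all, and 23 lay inside. With random lists not matched on abundance 12 lists changed sides, 6 of them to outside: proteasome, electron transport, glycolysis and fatty acid genes below and pathogen response and insulin-like peptide genes above. The others moved inside: small heat shock proteins, SKN-1 targets, innate immune effectors, ribosomal proteins, body wall muscle genes and F-box, MATH and BTB genes. Genes of a list are not independent replicates, so these percentiles describe the 2 conditions as deposited and are not p-values. The Fisher's exact tests treat genes as independent, so their p-values carry the same limit. Of the 66 called loci 30 belonged to at least 1 list and 36 to none.

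**Figure D4:**
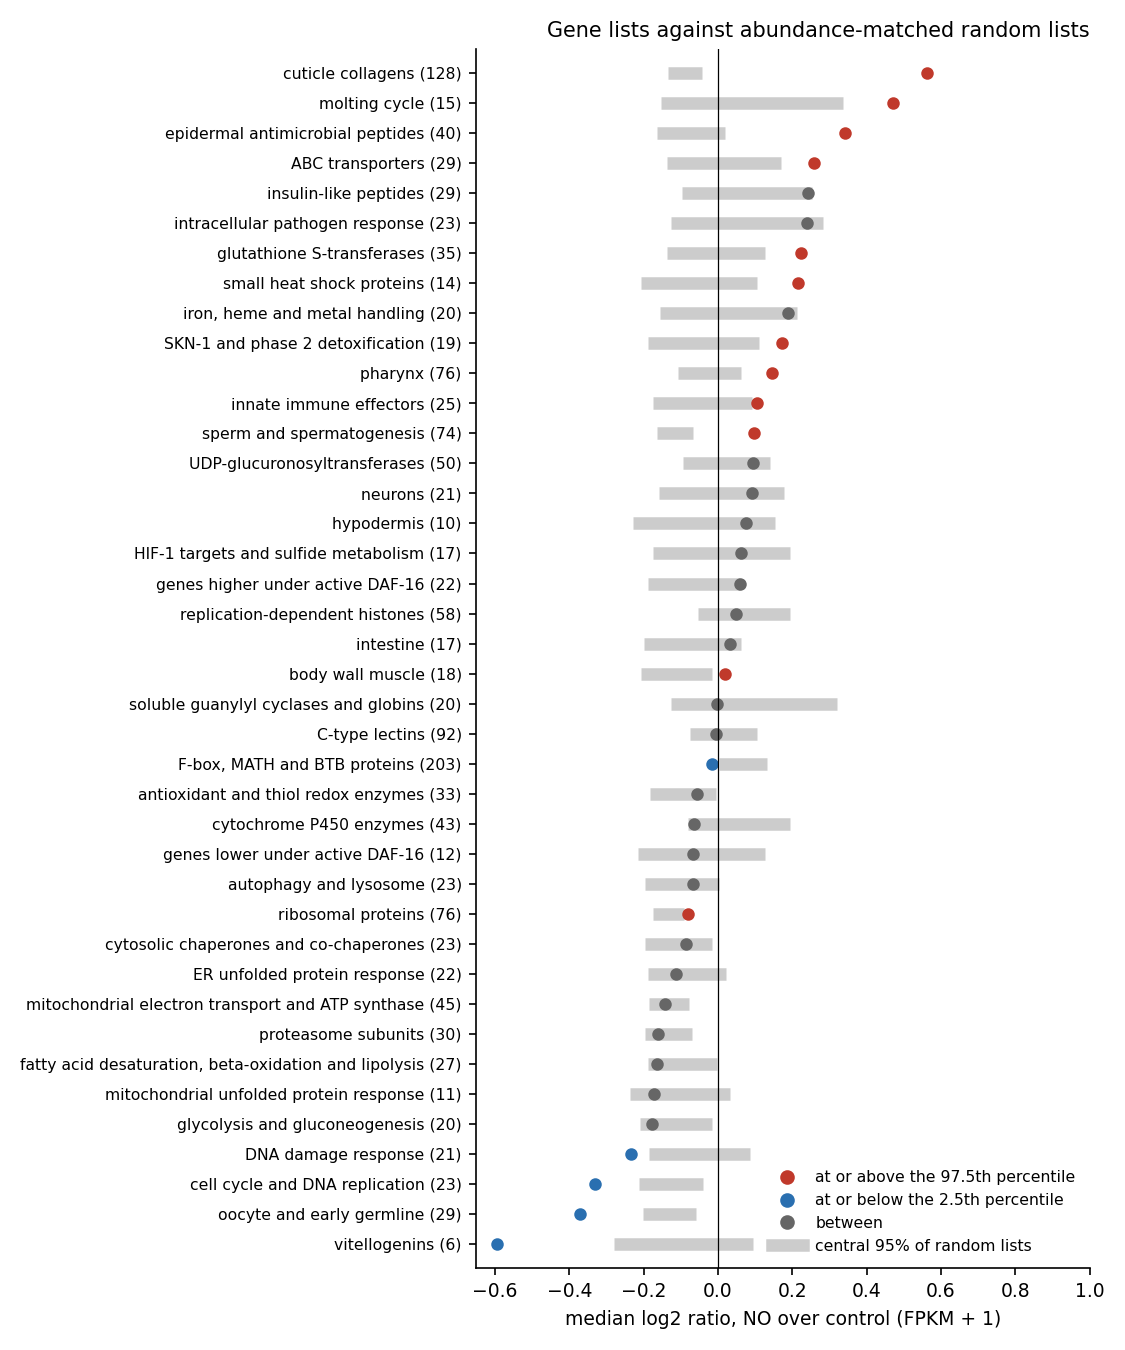
Median log2 ratio of NO over control, computed on FPKM + 1 (horizontal axis), for the 40 gene lists, with the number of measured loci in parentheses. Grey bars span the central 95% of 10000 abundance-matched random lists, 12 red medians lie above and 5 blue medians below that range, and 23 grey medians lie inside.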

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

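Settings that leave out joined, duplicate, ribosomal RNA or under 1 FPKM loci, or centre on abundance bins, were chosen only after the data were seen. The 66 calls (64 higher) became 42 (40 higher) at an adjusted p of 0.01 and 90 at 0.1. The other settings gave 63 to 88 calls, 88 after centring on the median of each abundance bin, where all 66 were among them, and 2 loci were lower in each of these. The median log2 ratio of the 64 higher loci was 2.17, and 2.21 to 2.44 under other pseudocounts or centring. Of 202 named loci 0 called ones reversed. Medians at or below the lower 2.5% of random lists numbered 8 with unmatched random lists against 5 with matched ones, the cause being the abundance trend that matching removes. The F-box, MATH and BTB median reversed to 0.030 without the filter on low expression, from -0.016, and the cause was not tested. Without matching, small heat shock proteins lay at percentile 96.2, SKN-1 targets at 96.1, innate immune effectors at 92.5, F-box, MATH and BTB genes at 71.8, body wall muscle genes at 68.25 and ribosomal proteins at 11.3, all inside the central 95%. The same setting moved 6 lists outside it, namely proteasome subunits (percentile 1.04), electron transport (0.98), glycolysis (1.79), fatty acid genes (1.55), pathogen response (99.1) and insulin-like peptides (99.65). With identical loci counted once the Fisher's exact test of small heat shock proteins gave an adjusted p of 0.00034, from 8.04e-06. At a minimum of 10 FPKM, genes higher under active DAF-16 reached the 100th percentile (median 0.31), genes lower under active DAF-16 turned from -0.07 to 0.09 (percentile 97.51), P450 genes went to -0.24 (percentile 0.27), UDP-glucuronosyltransferases lay at percentile 98.1, and molting genes (97.44) and F-box, MATH and BTB genes (10.6) lay inside the central 95%. With no filter on abundance the pathogen response list went from 0.24 to 0.50 (percentile 99.99), genes higher under active DAF-16 to percentile 99.6 and P450 genes to percentile 1.36. Of the 40 lists 12 changed sides of the central 95% without matching and 4 without joined loci. No paired analysis was possible because the table holds 1 value per condition. For that reason other size factors, DESeq2, leaving out replicates and an estimated correlation were not run. A planned setting without a filter on low expression equals the deposited calls. Depth is unknown, and simulated changes of log2 1 were called in 6% of 50 genes, so most changes of that size would be missed.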

Other observations

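The tests on an abundance trend and on carry-over of unselected RNA were chosen only after the results they measure were seen, while those on stage and on neighbouring genes were written before their own values were computed. Genes named in this paragraph, the rRNA loci and the gene pairs below that lie outside the naming rule were chosen after their values were seen. In the authors' deposited table gpdh-1, a glycerol 3-phosphate dehydrogenase gene induced by high salt, rose from 13.5 to 54.3 FPKM (log2 fold 2.01, SE 0.45, adjusted p = 0.00436), and hmit-1.1, a proton-coupled inositol transporter gene, from 5.85 to 31.1 FPKM (log2 fold 2.41, SE 0.44, adjusted p = 4.35e-05). Their paralogs gpdh-2 (157 and 216 FPKM), hmit-1.2 (5.62 and 6.94 FPKM) and hmit-1.3 (16.7 and 14.1 FPKM) were not called. The sodium pump-type gene catp-3 rose 3.94-fold (adjusted p = 0.00296), the carboxylesterase gene cest-34 11.3-fold (adjusted p = 0.000611) and the phosphoglycolate phosphatase gene pgph-3 2.98-fold (adjusted p = 0.0173) in the deposited table. The largest deposited fold, 112.7 for the bestrophin gene best-2, started from 0.0536 FPKM and reached 6.04 FPKM (SE of log2 fold 1.62).

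More loci were listed at 0 in control only than in NO only, and most of them were noncoding. Of 659 loci listed at 0 in control only, 572 were noncoding and 64 protein-coding, against 244 and 33 of the 282 listed at 0 in NO only. None of these loci was called in the deposited table.

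The 2 lists of collagen and molting genes, higher after NO, and the 2 of yolk and oocyte genes, lower after NO, lay outside the central 95% of random lists matched on abundance, although the molting list, with 0 called genes, lay inside it among loci of at least 10 FPKM (percentile 97.44). These placements were known when the lists were picked out, so they give no separate test of the trend of fold with abundance as a cause. For the other lists they show only that the medians went beyond that trend as far as matching in 10 bins captures it. Worms at an earlier stage at harvest may account for the pattern, since 12 late oogenesis genes had a median log2 ratio of -0.47 and 21 distal germline genes one of -0.14, a difference of -0.33 that 0.012% of 100000 random splits matched. None of these genes belonged to a fixed list, the most abundant late oogenesis gene, cpg-1, was listed at 736 and 518 FPKM, and genes are not independent. Oocyte genes were already known to be lower as a list, so the low late oogenesis median alone gives little separate support. Cell cycle and DNA replication genes were also lower as a list (median -0.33), and the comparison was not set up to account for them. A direct effect of NO on the same genes and a delay caused by the treatment both stay open and were not tested, since the labels give no stage at harvest for each condition.

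Ribosomal RNA loci were higher after NO, with rrn-1.1 at 85.2 and 229 FPKM (adjusted p = 0.0101), rrn-1.2 at 105 and 280 FPKM and rrn-3.1 at 205 and 482 FPKM called in the authors' deposited table. Their folds were close (2.68, 2.67 and 2.35), and shared reads were not tested, so these 3 calls may not be separate signals. Carry-over of RNA without a poly(A) tail could raise several such classes, and the medians of 3 of 5 lay above the central 95% of matched random lists. These were rRNA (4 loci, median 1.34), tRNA (82 loci, median 0.61) and snoRNA (80 loci, median 0.47, 49 ratios above 0), but tRNA ratios split into 41 above and 41 below 0 (mean 0.26), and tRNA and snoRNA had 0 loci at an unadjusted p under 0.05. snRNA (41 loci, median 0.12) and histones (58 loci, median 0.05) lay inside. The histone class was not limited to RNA without a poly(A) tail, since it held variant genes such as his-72 and 4 loci that joined several genes. Its place inside therefore says little about carry-over. tRNA pseudogenes went the other way (31 loci, median -1.95), and the 5S rRNA gene rrn-4.1, chosen after its values were seen, was listed at 1.38 and 0.207 FPKM. Carry-over and a change in the worms cannot be told apart, because 3 of 5 lies between the bounds set for the test and no per-library values were analysed here.

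Some called genes lay next to each other in the gene order. Among the 61 called loci with a place in that order, 7 neighbouring pairs were found, where 10000 random sets matched on abundance held 0.21 on average and at most 4. The random sets were not matched for clustered gene families. Several pairs came from the hsp-16 and F44E5 heat shock clusters, which hold near-identical copies, so the excess over random sets may be overstated. Reads shared between near-identical copies could make such pairs, and 3 of the 7 had NO values within 5% of each other, but hsp-16.1 with hsp-16.48 are not near-identical copies, which leaves F44E5.4 with F44E5.5 and hsp-16.48 with hsp-16.49. The other 4 included argk-1 with cth-1 (49.1 and 156 FPKM after NO) and Y58A7A.4 with Y58A7A.5 (16.8 and 59.9 FPKM), so shared reads and shared regulation cannot be told apart for the pairs as a set. Regulation shared by neighbours stays a hypothesis that was not tested further.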
